A study of Mus musculus with 6 samples.

How the data were processed

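Bone RNA from female C57BL/6J mice aged 16 weeks was sequenced in 3 libraries from wild-type mice and 3 from mice lacking the miR-29cb2 cluster, which encodes the microRNAs miR-29b-2 and miR-29c. Per the labels' protocols, the bone was frozen on dry ice, RNA was extracted with Trizol, and libraries were built from total RNA with an Illumina TruSeq kit. Groups and replicate numbers were taken from the sample titles and genotype labels. The labels do not say which bone was taken, whether marrow was removed, or that each library came from its own animal, so p-values measure the spread between these libraries, which may be technical in part.

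The authors deposited a table of FPKM values (fragments per kilobase of exon, scaled for library size) for 54532 genes, with 1 column per library. Per the submitters' processing notes, Bowtie 0.12.2 and the mouse build mm10 were used. The counting tool, the annotation, the use of strand and the scaling behind the FPKM values are not given in the sources used here. Of the gene identifiers, 54495 matched the GENCODE M21 annotation, which supplied coordinates (mm10), exon lengths and 3′ UTRs, and 37 did not.

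The FPKM values of a gene, multiplied by its exon length, moved in fixed steps within each library. With a tolerance of 0.01 reads, 96.9% of the 29615 genes with a value above 0 gave whole reads in all libraries. The step sizes put the scaling divisors at 16578300 to 20596700 reads, and 16727100 to 20118000 reads were recovered per library. The divisors lay within -1.46% to 0.94% of median-of-ratios factors and within -6.88% to 7.79% of the recovered totals. Genes without whole reads made up 17.5% on chromosome 17, 47.3% on chromosome 18, 46.9% on chromosome 19 and 0.16% elsewhere, so read numbers for those chromosomes are incomplete. Counting error alone is covered by statements on reads.

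Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1. A fold change on this scale understates the change of low genes. Genes with a mean FPKM of at least 1 over the 6 libraries were kept, which left 13619. Groups were compared with limma (moderated variances with a trend on expression), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. All adjusted p-values printed for genes come from limma. The host transcript and its neighbours were also compared with a two-sided exact permutation test, whose smallest p for 3 against 3 libraries is 0.1.

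The gene lists, the tests, the named-gene rule and all but 3 of the alternative settings were fixed before the data were examined. Of 38 lists, 1 holds the deleted and sister loci and was read as levels, 1 (epidermis) had under 3 measured members, and 36 were tested. The tests were limma's camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, each adjusted over the 36 lists. List members were counted past the threshold over all genes and adjusted over the list alone. Genes with a miR-29 seed match in an annotated 3′ UTR (the 7mer TGGTGCT, or the 8mer TGGTGCTA) were compared with other genes by camera and by the difference of median log2 change, set against 139 other 7mers of the same base composition.

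The genes named are those of the locus, the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, and up to 3 members per list with the smallest p. Immunoglobulin and T cell receptor segments, predicted genes and pseudogenes were counted and not named, except the host transcript and its neighbour Gm37366. This left 22 higher and 14 lower genes out of the ranking by type. Some genes outside the rule are named. Cdk6, Plod3 and Chil3 are marked as such where they appear, and others, such as Calr and Dgat2, are not. A gene that the rule names among the list members is not reported here.

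The limma and camera steps were tested on simulated data with 12928 genes and a dispersion of 0.0235. Of the genes simulated with a change of 1.5-fold, 6.25% were recovered, against 82.0% at 2-fold and 100% at 4-fold and 8-fold. Of 163 calls 19 were false, a larger share than the threshold of 0.05. Of 20 unchanged lists, 0 were called. Those lists held random genes simulated independently of one another. The result therefore does not cover lists of correlated genes, such as the ribosomal proteins, with an estimated correlation of 0.92. Alternatives covered the pseudocount, the filter on low values, the scaling, the variance model, library weights, the replicate block and leaving out each library. A further 3 were chosen after seeing the data: limma's voom on the recovered reads, removal of each library's trend with exon length, and leaving out both libraries that stood apart from the rest. Replicates of 1 group differed by far more than sampling noise (chi-square per degree of freedom of 12.9 to 73.2), so no library was counted as a repeat. Figures were drawn with matplotlib 3.10.9.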

Results

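RNA levels were measured in bone from 3 wild-type and 3 miR-29cb2 knockout libraries, all labelled as female mice aged 16 weeks. Recovered reads ranged from 16727100 to 20118000 per library, and 13097 to 14009 genes reached an FPKM of 1. Wild-type replicate 2 and knockout replicate 1 stood apart from the others. Their FPKM totals were 489576 and 487102, against 355787 to 404994 in the other 4 libraries, and their deviations from the group mean fell with exon length (Spearman's rho across genes of -0.42 and -0.45). Across genes, which are not independent replicates, Pearson's r of log2 values between libraries was 0.92 to 0.98.

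To check the labels, the deleted locus was examined first. The noncoding host transcript of the cluster, A330023F24Rik (ENSMUSG00000096929), was higher in the knockout. It lies on chromosome 1 from 194976375 to 195037904 on the plus strand (mm10). Its level was 0.162 ± 0.0315 FPKM in wild type and 3.28 ± 0.788 in knockout bone (SD, n = 3), a ratio of 20.2, from 89 and 1580 reads. All 3 knockout libraries lay above all 3 wild-type libraries, the log2(FPKM + 1) difference was 1.87, and the two-sided exact permutation p was 0.1, the smallest possible with n = 3. In limma over all genes its adjusted p was 0.00676. The microRNA genes Mir29b-2 (195037040 to 195037120) and Mir29c (195037547 to 195037634), at the 3′ end of the host, were listed at 0 in all 6 libraries. The sister-locus gene Mir29b-1 was also listed at 0 throughout, and Mir29a had 1 read, in knockout replicate 3. Mature microRNAs are too short for this library type, so these zeros do not show the deletion. The deleted interval and any sequence left in its place are not given in the sources used here. The labels could therefore not be checked by loss of a transcript.

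Genes beside the host moved less. Cd46, which encodes a complement regulator and overlaps the 3′ end of the host on the opposite strand (195036826 to 195092249), stood at 0.490 ± 0.157 and 0.514 ± 0.220 FPKM (exact permutation p = 0.9, n = 3). Because the use of strand is not known, reads of this overlap cannot be assigned. Cr1l had a ratio of 1.04, Cr2 of 1.56, Cd34 of 0.756 and Plxna2 (1.25 ± 0.457 and 0.608 ± 0.157 FPKM), which lay below the limma filter, of 0.485. The flanking-gene list had 8 measured members, of which Cd55 starts at 130439027 on chromosome 1 and so does not flank the locus. Of the 8, 1 rose, the glucocorticoid-activating enzyme Hsd11b1, which starts at 193221634. It went from 9.97 ± 1.23 to 17.9 ± 2.74 FPKM (log2 change 0.78, limma adjusted p = 0.0357). When adjusted over the list alone, 2 members rose. Traf3ip3 had a log2 change of 0.39 and did not pass over all genes. The list passed by fry (adjusted p = 0.00383), which does not compare it with other genes, and not by camera (adjusted p = 0.103).

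**Figure D1:**
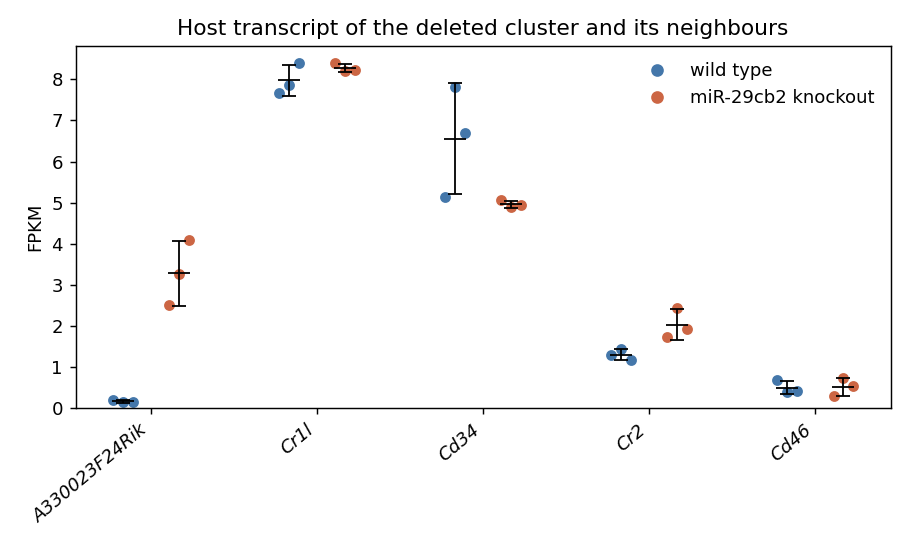
FPKM of the host transcript A330023F24Rik and 4 neighbouring genes in each library, wild type in blue and knockout in orange, with bars for the mean and SD of 3 libraries. The host transcript averages 0.162 FPKM in wild type and 3.28 in knockout bone.

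To find which genes differ between the genotypes, all expressed genes were compared. Genes of cartilage, fat and tendon showed the largest falls in knockout bone. Cfd, the complement factor D secreted by fat cells, fell from 390.0 ± 106 to 20.5 ± 10.7 FPKM (SD, n = 3; log2 change -4.28, limma adjusted p = 0.00712). Col2a1, the main collagen of cartilage, fell from 96.4 ± 13.4 to 9.92 ± 4.73 FPKM (log2 change -3.27, limma adjusted p = 0.010). Outside immunoglobulin segments, the largest rise past the threshold was that of Lipg, an endothelial lipase, from 2.20 ± 0.666 to 19.7 ± 2.23 FPKM (log2 change 2.70, limma adjusted p = 0.00349).

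The other genes named for the largest falls were mostly cartilage genes. They were Prg4, the joint lubricant lubricin (log2 change -4.08), Cytl1 (-3.92), Clec3a (-3.73), Cnmd, which encodes chondromodulin (-3.45), Comp, cartilage oligomeric matrix protein (-3.42), Chad (-3.36), and the collagen IX chains Col9a2 (-3.30) and Col9a3 (-3.16). The other genes named for the largest rises were Prok2, which rose from 0.792 ± 0.505 to 7.41 ± 1.03 FPKM (log2 change 2.26), Dmkn (1.89), the proteoglycan Vcan (1.87), Ggt1 (1.83), Trim63, a muscle ubiquitin ligase (1.80), Sdf2l1, a protein of the endoplasmic reticulum (1.69), Mir6942 (1.64), Ctsg, a neutrophil granule protease (1.63), and Serpina3b (1.52). Mir6942 lies within the gene Zkscan3 on the same strand, so its reads cannot be assigned to it.

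In all, 703 of 13619 genes passed, 183 higher and 520 lower in the knockout, and 312 of the lower and 56 of the higher genes changed at least 2-fold on the log2(FPKM + 1) scale. At an unadjusted p under 0.05 there were 2812 genes. The groups did not overlap in 28.4% of genes, against 10% by chance. The count fell when any library was left out. It was 62 without wild-type replicate 1, 252 without wild-type replicate 2, 418 without wild-type replicate 3, 159 without knockout replicate 1, 78 without knockout replicate 2 and 339 without knockout replicate 3. Without both libraries that stood apart, an alternative chosen after seeing the data, 239 genes passed, 86 higher and 153 lower.

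**Figure D2:**
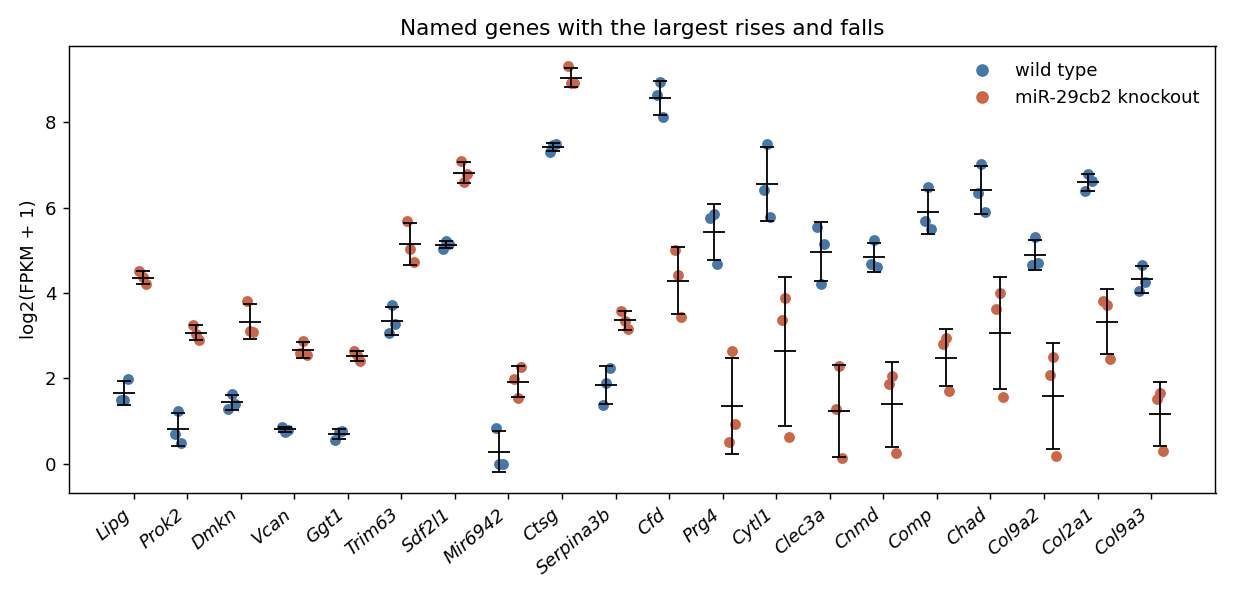
log2(FPKM + 1) per library for the 10 named genes with the largest rises and the 10 with the largest falls, wild type in blue and knockout in orange, with bars for the mean and SD of 3 libraries. Knockout replicate 3 lies lowest of the knockout libraries for several cartilage genes, and Cfd changes by -4.28.

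To describe the tissues and pathways behind these genes, 36 fixed lists were tested. By camera 24 passed, 21 lower and 3 higher. By fry 16 passed, the flanking genes and the Wnt feedback targets among them, which did not pass by camera, and with an estimated correlation 0 passed by camera, where the lowest adjusted p was 0.144 and 8 lists had an unadjusted p under 0.05. The camera calls of collagen biosynthesis, skeletal muscle, neutrophil and B cell genes were lost by fry. The adjusted p with an estimated correlation is given beside each list below.

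Markers of cartilage, tendon, fat and nerve sheath fell together. In the chondrocyte list 14 of 17 measured members fell and 17 when adjusted over the list alone, with a median log2 change of -3.16 (adjusted p = 0.223 with an estimated correlation). Matn3 went from 12.2 ± 4.71 to 0.509 ± 0.447 FPKM (SD, n = 3). Knockout replicate 3 held the lowest cartilage levels, with members at a median of -0.77 from their group means on the log2 scale. In the tendon and fibroblast list 9 of 11 members fell and 9 when adjusted over the list alone (median -1.69, adjusted p = 0.149 with an estimated correlation). These included Fmod (29.1 ± 3.08 to 2.98 ± 1.25 FPKM), Dpt (log2 change -2.84) and the tendon marker Tnmd (-1.69). In the adipocyte list 11 of 14 members fell, or 13 adjusted over the list alone (median -1.51, adjusted p = 0.149 with an estimated correlation), among them the lipid droplet genes Plin1 (8.12 ± 2.25 to 0.340 ± 0.188 FPKM) and Cidec (log2 change -2.89). In the Schwann cell list 4 of 6 members fell, and 4 adjusted over the list alone (median -1.20, adjusted p = 0.149 with an estimated correlation), including the myelin gene Pmp22 (log2 change -1.20).

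Bone and muscle genes were also lower. In the osteoblast list 9 of 22 members fell and 21 adjusted over the list alone (median -1.18, adjusted p = 0.239 with an estimated correlation). Smpd3 went from 12.8 ± 2.33 to 2.55 ± 0.429 FPKM (SD, n = 3), and Panx3 (log2 change -1.88) and Cdh11 (-1.0) also fell. Of 7 osteocyte genes 3 fell and 6 adjusted over the list alone (median -0.89, adjusted p = 0.239 with an estimated correlation), namely the mineralization genes Phex (log2 change -1.09) and Dmp1 (-1.03), and Pdpn (-0.83). Of 18 osteoclast genes 1 fell, the proton pump subunit Atp6v0d2 (21.3 ± 5.63 to 6.74 ± 1.29 FPKM), and 9 fell adjusted over the list alone (median -0.35, adjusted p = 0.276 with an estimated correlation). Acp5, the tartrate-resistant phosphatase, had a log2 change of -1.50 and did not pass (limma adjusted p = 0.0587). Of 20 skeletal muscle genes 5 fell and 15 adjusted over the list alone (median -1.02, adjusted p = 0.282 with an estimated correlation), including Casq1 (log2 change -1.94), Myh2 (-1.53) and Myl1 (-1.19).

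Among matrix genes and published miR-29 targets more fell than rose. Of 22 matrix targets 12 fell, 22 fell adjusted over the list alone and 0 rose (median -1.02, adjusted p = 0.144 with an estimated correlation). Col6a3 went from 6.07 ± 1.03 to 1.39 ± 0.261 FPKM (SD, n = 3), and Col3a1 fell as well (log2 change -1.67). Of 38 other targets 5 fell, among them Tgfb3 (log2 change -1.45), Pdgfrb (-0.62) and Igf1 (-0.52), and 7 fell and 1 rose adjusted over the list alone. The gene that rose on that count was Cdk6 (0.65), named outside the rule after its values were seen. Their median was 0.01 while their mean was -0.15, and the list did not pass (camera adjusted p = 0.0667). Of 23 genes of collagen biosynthesis 6 fell and 1 rose, against 15 and 3 adjusted over the list alone (median -0.64, adjusted p = 0.411 with an estimated correlation). Those that fell include the crosslinking enzymes Loxl1 (log2 change -1.24) and Lox (-1.31) and the procollagen protease Adamts2 (-0.76). Plod3, named outside the rule after its values were seen, was the gene that rose (0.60). Of 13 matrix proteases and inhibitors 4 fell, with 8 lower and 1 higher adjusted over the list alone (median -0.60, adjusted p = 0.239 with an estimated correlation), including Timp2 (log2 change -0.99), Mmp2 (-1.16) and Mmp14 (-1.28).

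Signalling genes were lower by camera in 2 of 4 lists. Of 10 Wnt antagonists 4 fell and 7 adjusted over the list alone (median -1.05, adjusted p = 0.207 with an estimated correlation), including Frzb (log2 change -1.53), Dkk3 (-1.17) and Wif1 (-1.17). Of 22 TGF-beta and BMP genes 5 fell and 9 adjusted over the list alone (median -0.51, adjusted p = 0.149 with an estimated correlation), including Ccn2 (log2 change -2.01), Tgfbr3 (-0.68) and Tgfb3. Of 4 Wnt feedback targets 2 fell, Ccnd1 (-0.87) and Apcdd1 (-0.71), and adjusted over the list alone 2 fell and Myc rose (0.42). The list was lower by fry (adjusted p = 0.0285) and did not pass by camera (adjusted p = 0.200). Of 8 osteoclast-regulating ligands 2 fell, the cytokine Il1b (-1.39) and the decoy receptor Tnfrsf11b (-1.22), with 2 lower and 1 higher adjusted over the list alone. Tnf had a log2 change of 0.90 and did not pass, and neither did the list (camera adjusted p = 0.176).

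Marrow blood-cell lists moved in both directions. Of 18 neutrophil genes 4 rose and 7 adjusted over the list alone (median 0.56, adjusted p = 0.361 with an estimated correlation). The granule proteins Ctsg (171 ± 11.0 to 535 ± 88.7 FPKM, SD, n = 3), Mpo (214 ± 21.4 to 444 ± 58.3) and Prtn3 (314 ± 91.4 to 884 ± 189) rose. The other was Chil3 (log2 change 1.29), named outside the rule after its values were seen. Of 18 B cell genes 2 fell, the surrogate light chain genes of B cell precursors Vpreb1 (log2 change -2.32) and Igll1 (-2.06), and 4 fell adjusted over the list alone (median -0.44, adjusted p = 0.411 with an estimated correlation). Ebf1 had a log2 change of -0.62 and did not pass. Of 8 plasma cell genes Sdc1 fell (-1.09), with 3 lower and 1 higher adjusted over the list alone (median -0.50, adjusted p = 0.482 with an estimated correlation), while Xbp1 had a log2 change of 0.60 and did not pass. The call of this list was also lost by fry, with array weights, abundant transcripts removed, voom or the length trend removed, and without wild-type replicate 1 or 2, knockout replicate 1 or 3, or both libraries that stood apart (medians -0.64 to -0.069 over all settings). Of 15 endothelial genes 2 fell, Cdh5 (-0.75) and Kdr (-0.60), and 10 adjusted over the list alone (median -0.47, adjusted p = 0.144 with an estimated correlation). Of 12 marrow stromal genes 2 fell, Prrx1 (-0.85) and Pdgfrb, and 5 adjusted over the list alone (median -0.33, adjusted p = 0.239 with an estimated correlation). Of 12 megakaryocyte genes 0 passed in limma, and 0 adjusted over the list alone, but the list was higher by camera (median 0.33, adjusted p = 0.501 with an estimated correlation), with Ppbp at 615 ± 203 and 893 ± 77.3 FPKM. That call was also lost by fry, with array weights, and without wild-type replicate 1 or 2, knockout replicate 3, or both libraries that stood apart (medians 0.061 to 0.57). The erythroid (median 0.06), T and NK cell (-0.13) and monocyte and macrophage (-0.12) lists did not pass (camera adjusted p = 0.939, 0.489 and 0.409). Of 17 monocyte and macrophage genes Csf1r, the receptor of colony-stimulating factor, fell (log2 change -0.68), with 2 lower and 2 higher adjusted over the list alone. Cd163 had a log2 change of 0.91 and did not pass. Of the erythroid genes Rhag had a log2 change of 0.18, and of the T and NK cell genes Nkg7 one of 0.88; neither list had a member past the threshold, over all genes or over the list alone.

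Response lists differed between genotypes as well. Of 21 interferon-stimulated genes 4 fell and 8 adjusted over the list alone (median -0.52, adjusted p = 0.276 with an estimated correlation). Ifit3 went from 9.41 ± 0.426 to 1.71 ± 0.703 FPKM (SD, n = 3), and Rtp4 (log2 change -1.49) and Ifit1 (-1.11) fell. Of 13 circadian genes 4 fell, including the clock output gene Dbp (-1.65), Nr1d2 (-0.82) and Bhlhe41 (-0.79), with 5 lower and 1 higher adjusted over the list alone (median -0.19, adjusted p = 0.414 with an estimated correlation). The circadian call was lost by fry and without knockout replicate 1. Of 13 immediate-early genes Egr1 fell (-1.08) and 3 fell adjusted over the list alone (median -0.29, adjusted p = 0.482 with an estimated correlation), and the list's call was lost by fry, with array weights and without wild-type replicate 2 or both libraries that stood apart. Of 11 heat shock genes the chaperone Hsp90aa1 rose (0.74), and 1 adjusted over the list alone (median 0.37, adjusted p = 0.545 with an estimated correlation), and the list's call was lost by fry and without wild-type replicate 1 or 3 or knockout replicate 1. Of 27 oxidative phosphorylation genes 0 passed in limma, over all genes or over the list alone, and the list was lower by camera (median -0.19, adjusted p = 0.701 with an estimated correlation). That call was lost by fry and without knockout replicate 2, knockout replicate 3 or both libraries that stood apart. Sdhb had a log2 change of -0.44. The glycolysis and hypoxia list did not pass (median 0.08, camera adjusted p = 0.205). In it Egln3 (log2 change 1.22) and Pgam1 (0.94) rose and an Aldoa entry that shares its symbol with a second one fell (-1.46), with 5 higher and 1 lower adjusted over the list alone. The cell division (median 0.13), ribosomal protein (0.13), cholesterol synthesis (0.022) and DNA methylation (0.14) lists did not pass either, with limma camera adjusted p-values of 0.105, 0.0730, 0.939 and 0.205. None of the last 4 lists had a member past the limma threshold, over all genes or over the list alone. The smallest p in them belonged to Bub1 (log2 change 0.44), Rpl11 (0.30), Insig1 (-0.51) and Dnmt3b (0.41).

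**Figure D3:**
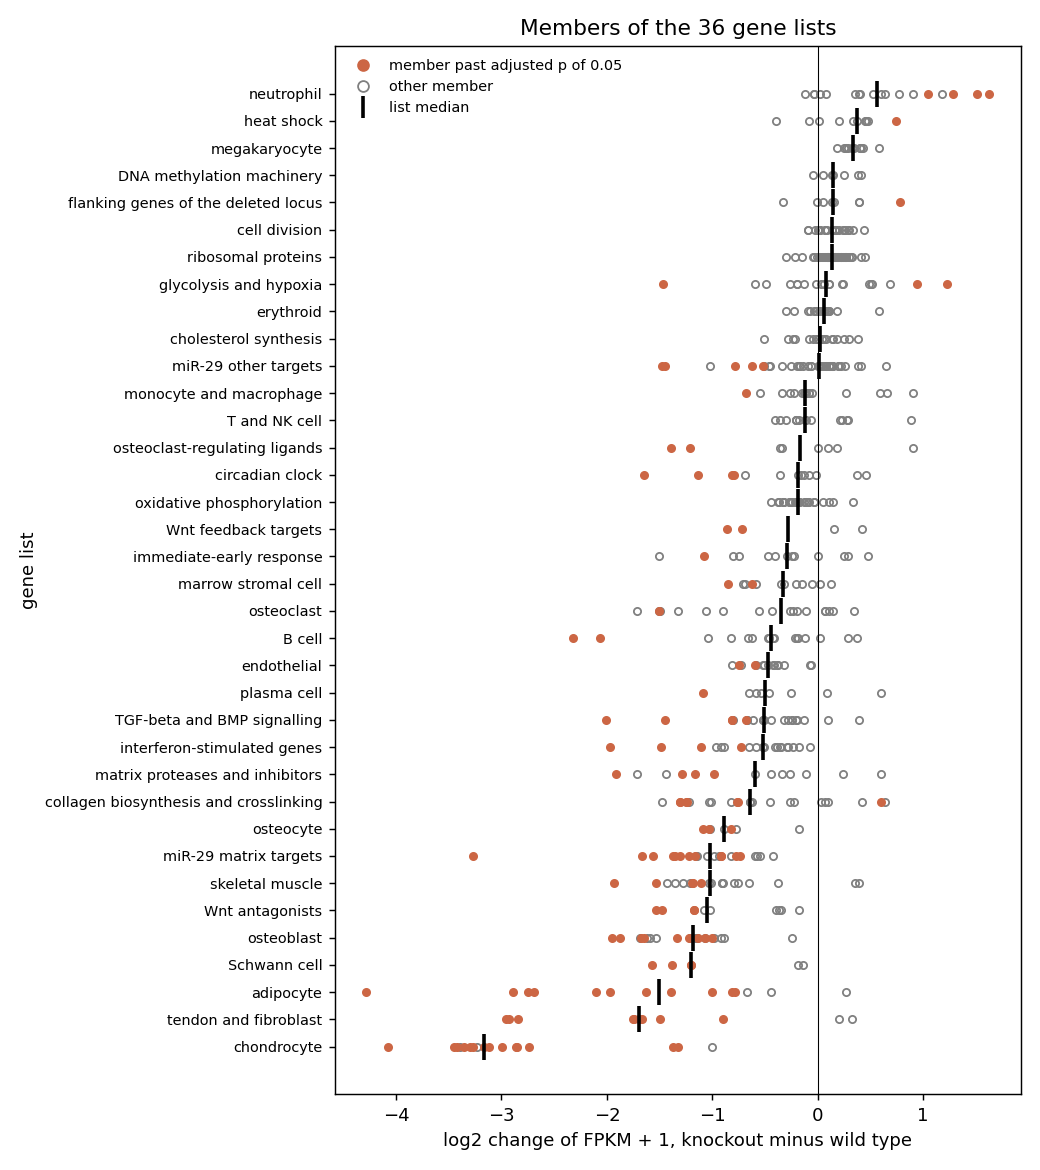
log2 change of FPKM + 1, knockout minus wild type, for each measured member of 36 gene lists, with filled points for members past a limma adjusted p of 0.05 and a bar for the list median. Medians run from -3.16 for chondrocyte to 0.56 for neutrophil genes.

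To ask whether genes with miR-29 seed matches rose, 3′ UTRs were searched. Genes with a site did not rise as a set. The 1791 genes with a 7mer or 8mer match had a median log2 change of 0.064, and the 9871 without had 0.054, a difference of 0.010 (limma camera adjusted p = 0.994). Of 139 permuted 7mers 31 gave a difference as high, and their differences ran from -0.036 to 0.038. Of the genes with a site 15 rose and 89 fell. The 361 genes with an 8mer differed by -0.027 (limma camera adjusted p = 0.347), with 3 higher and 32 lower, so that 9.70% were called against 5.57% of genes without an 8mer. The sign of the 7mer difference turned when wild-type replicate 2 (-0.035), knockout replicate 2 (-0.0035) or knockout replicate 3 (-0.015) was left out.

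**Figure D4:**
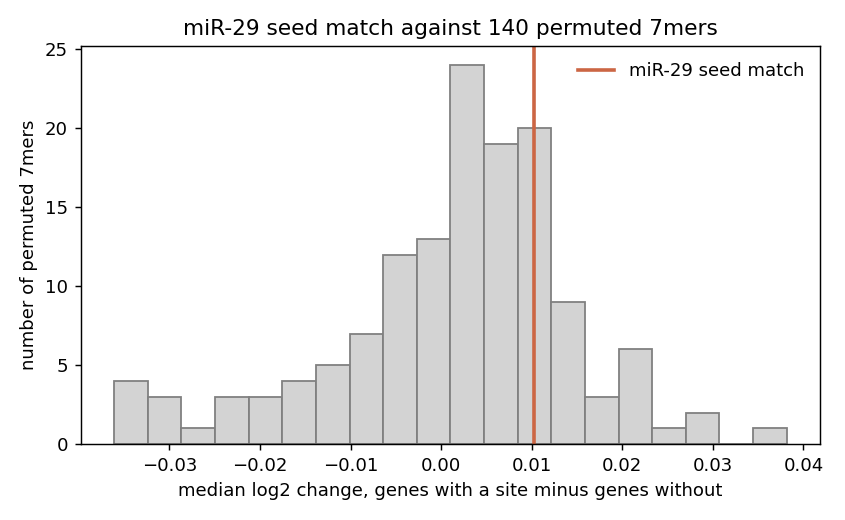
Difference of median log2 change between genes with and without a 3′ UTR site. Grey bars (number of 7mers) hold the 139 permuted 7mers and the miR-29 seed match itself, which the title counts among them. The line marks the seed match (0.010). The line lies inside the range of the permuted 7mers, -0.036 to 0.038.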

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

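The settings voom, removal of the exon length trend and leaving out both libraries that stood apart were chosen after seeing the data. In every setting run, all of the 703 genes that were still tested kept their direction. For many settings this was fixed in advance. The groups of all called genes, 183 higher and 520 lower, did not overlap, so leaving out libraries could not turn their direction. The filter, the variance model and the replicate block could not either, as they leave the log2 change as it is. The causes of the changes below were not tested unless fewer genes or libraries were used. The number of genes past the threshold depended on the setting. It was 143 without a filter on low values (43 higher, 100 lower; 29615 genes tested), 365 at a mean FPKM of at least 5 (232 lower; 8318 genes tested), 3354 with array quality weights (1551 higher, 1803 lower), 1217 with the exon length trend removed (378 higher, 839 lower) and 239 without both libraries that stood apart (86 higher, 153 lower). It lay between 636 and 821 with the other pseudocount, scalings, variance model and voom. Leaving out 1 library gave 62 (wild-type replicate 1) to 418 (wild-type replicate 3) genes, 14 to 79 higher and 48 to 348 lower. The lists past camera's threshold numbered 21 to 26 when 1 library was left out, 16 by fry and 0 with an estimated correlation.

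With the replicate number as a block, 127 genes passed (19 higher, 108 lower). Deviations of libraries with the same number correlated at -0.49, -0.27 and 0.16, which gives no sign of pairing by number. These deviations also ran with exon length, with Spearman's rho from -0.45 (knockout replicate 1) to 0.41 (wild-type replicate 1). The correlations therefore cannot exclude that the numbers pair the samples.

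The host transcript's difference was 3.67 with a pseudocount of 0.1 and 1.73 to 2.0 when 1 library was left out. The seed difference ran from -0.035 (without wild-type replicate 2) to 0.046 (without knockout replicate 1), and it was -0.0035 and -0.015 without knockout replicates 2 and 3, -0.0014 with the length trend removed and -0.027 for 8mers alone.

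Apart from oxidative phosphorylation, lists and genes whose median or log2 change turned sign had not passed by camera or limma in the main setting. Oxidative phosphorylation had passed by camera and Wnt feedback targets by fry. Some lists gained a camera call in other settings. miR-29 other targets passed with no filter (camera adjusted p = 0.047), without wild-type replicate 2 (0.0074) or knockout replicate 2 (0.043), and with both libraries left out (0.046). Erythroid genes passed with array weights (camera adjusted p = 0.045). Ribosomal proteins gained a call in 8 of 20 settings and cell division in 3. For miR-29 other targets the medians were -0.0042 (no filter), -0.013 (quantile normalization), -0.021 (median-of-ratios scaling), -0.089 (abundant transcripts removed), -0.066 (array weights), -0.033 (length trend removed), -0.072 (both libraries left out), and -0.14 to 0.051 when 1 library was left out, below 0 without wild-type replicate 2 and without knockout replicates 1 (-0.0087), 2 (-0.047) and 3 (-0.068). Cholesterol synthesis gave -0.020 (mean of at least 5), -0.0036 (median-of-ratios), -0.062 (abundant transcripts removed), -0.040 (array weights), -0.011 (length trend), -0.013 (both left out) and -0.019 to 0.11 when 1 library was left out. Erythroid genes gave -0.046 (abundant transcripts removed), -0.17 (array weights), -0.061 (both left out), and -0.077 to 0.17 when 1 library was left out (-0.012 without knockout replicate 1). Others were osteoclast-regulating ligands at 0.051 (mean of at least 5), glycolysis and hypoxia at -0.014 (abundant transcripts removed), cell division at -0.084 and Rhag at -0.054 (array weights), Wnt feedback targets at 0.17 (voom), and T and NK cells at 0.024 (both left out). Leaving out 1 library gave ribosomal proteins -0.067 to 0.29 (-0.015 without wild-type replicate 1), oxidative phosphorylation -0.35 to 0.033 and Hba-a2 -0.068 to 0.96. Among named genes and settings, 1647 pairs stayed on the same side of the threshold, 439 lost the call and 52 gained it, with no other turn of direction than those given.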

Other observations

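The tests on common tissue loss, on relative change within the cartilage, fat and muscle lists, on Cd46 and on the region were chosen after the result was seen, and so were the glucocorticoid and endoplasmic reticulum gene lists. The other tests were written before their results.

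Genes of protein folding in the endoplasmic reticulum were higher in knockout bone. Calr went from 164 ± 19.8 to 318 ± 52.5 FPKM (SD, n = 3; log2 change 0.94, limma adjusted p = 0.0390), Hspa5 from 112 ± 9.46 to 211 ± 33.2 (0.90, limma adjusted p = 0.0337) and Pdia6 from 51.5 ± 9.44 to 106 ± 21.6 (1.02, limma adjusted p = 0.0360). The list was drawn up because Sdf2l1 and Hyou1 ranked among the risers, and both were left out of it. Of its 20 genes 17 lay above 0 and 5 rose, with a median of 0.52 (limma camera adjusted p = 8.72e-07, fry adjusted p = 0.0341, over the 2 lists), but the camera adjusted p with an estimated correlation was 0.213. A wider rise of endoplasmic reticulum stress genes is one hypothesis. Against a full stress response, Ddit3 (log2 change -0.15) and Herpud1 (-0.15) did not rise. The neutrophil list moved the same way (median 0.56), and its camera call was lost with an estimated correlation and by fry. The cell type that carries the change was not tested.

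A wider rise of glucocorticoid-responsive genes was tested because Fbxo32 and Trim63, muscle ubiquitin ligases, were higher. The result was negative. The median of 20 measured genes without these was 0.019 (limma camera adjusted p = 0.803, fry adjusted p = 0.450), although Fkbp5 (log2 change 0.87) and Il1r2 (1.19) passed. Calls also did not gather around the deleted locus. Of 30 genes within 5 Mb 1 was called, Hsd11b1, or 3.33%, against 5.16% of other genes (two-sided Fisher's exact test p = 1), too few genes to exclude a passenger interval.

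The first pattern weighed is the lower level of cartilage, fat, tendon and muscle genes. Scaling of the libraries by abundant transcripts is argued against, because all 34 called cartilage, fat and tendon genes stayed lower under 3 other scalings. Less fat with its genes unchanged relative to one another was tested by departures from the list mean. Of the abundant fat genes 80.0% departed, for example Cfd by -2.75 and Dgat2 by 1.89 (log2). Several of these genes are also expressed outside fat, which would hold up their levels under less fat. Such departures could therefore arise either way, so the test cannot decide whether there was less fat. One common loss of all tissue outside the marrow, equal for cartilage and muscle, is argued against only under a condition given below. The cartilage minus muscle difference was -4.00, -4.09 and -7.60 in the knockout libraries and -2.63 to -2.38 in wild type (log2). An equal loss of any size leaves this difference unchanged if the genes of both lists come from no other tissue, which was not tested. Under that condition, the departure of the nearest knockout library, by 11.1 wild-type SDs, goes against such a loss. That SD comes from 3 wild-type libraries, and the rule based on it was added after the result was seen. However, the mean change of -2.76 was 1.90 pooled SDs, under the 2 first set. Without knockout replicate 3 the mean change was -1.57. For cartilage 0% of members departed, with a wide spread of relative change (SD 1.02), and for muscle 11.1%. Less of these tissues, in equal or unequal amounts, therefore cannot be told apart from an effect of genotype. What was dissected with the bone is not given in the sources used here, and the genotype is an untested biological explanation.

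The second pattern is the higher host transcript. Reads of the overlapping antisense gene are argued against, since Cd46 had a ratio of 1.05. A rise of the whole region was first tested by asking whether any neighbour with at least 20 reads rose 2-fold, and Gm37366 did, with a ratio of 2.29 from 7 and 14 reads. Because a single gene with so few reads says little about a region, a second test was added after that result, and the median ratio of the 7 neighbours was 1.05 (0.485 for Plxna2 to 2.29), which argues against a rise of the neighbours as a set; a local rise that includes Gm37366 stays open. Within the host interval 4 other listed genes had 7 reads in wild type and 27 in knockout libraries, and an effect of the deletion on the making or processing of the host transcript may account for the rise but was not tested.

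The third pattern is the absence of a rise among genes with miR-29 sites. Loss of connective tissue hiding a rise was tested within 5 connective tissue lists, where 13 members with a site lay 0.055 above 58 without, centred per list (permutation p = 0.616), so it cannot be told apart with so few genes. The sister locus, which encodes miR-29a and miR-29b-1, was not measured at the level of mature microRNAs and stays open as an untested biological explanation.

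With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 703 genes and the highest other 0, and 1 of the splits gave as many. For the gene lists, 2 of the 10 splits gave as many: the real one passed 24 lists and another passed 24 as well, so the number of lists past camera's threshold does not set the genotypes apart from other groupings. For the seed difference 9 of 10 splits gave one as large, with 0.010 for the real split and 0.091 for the highest other.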
